A study of Mus musculus with 24 samples.

How the data were processed

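Total RNA from whole brain of 24 mice aged 14 months was measured with the nCounter Neuropathology panel, in which barcoded probes bound to each transcript are counted without amplification. The mice were wild type (WT), Grn knockout (GRN KO), Trem2 knockout (TREM2 KO) or knockout for both genes (GRN/TREM2 KO), with 6 mice per genotype, 3 of each sex. Groups and sex were taken from the labels, and replicate numbers follow the order of the samples, so they pair nothing. The deposited table held 770 panel genes, 8 negative controls and 6 positive controls, and every sample column was matched to its sample. Of the 770 symbols, 763 were current RefSeq symbols (GRCm38.p6 annotation, used for names only) and 7 were older synonyms. No coordinates are given, because an nCounter value belongs to a probe whose position is not given in the sources used here.

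The authors deposited normalized signal values on a linear scale, and the software, scaling genes and background handling are not given in the sources used here. The deposited values themselves show that the sexes were handled differently. In the 12 females the lowest genes lay near 1 and the negative controls averaged 2.96, as a subtracted background would leave them. In the 12 males the lowest genes lay at exactly 20, as a floor without subtraction would leave them. The male negative controls averaged 17.69 and reached down to 3, below that floor, and all 6 positive controls held whole numbers in each male. These control rows thus appear neither floored nor scaled, so their mean is not on the same footing as that of the females. The mean of 12 housekeeping genes was 9.39 (log2, SD 0.025) in females and 9.19 (SD 0.023) in males, so the sexes were also on different scales. Per the design text of the series, the normalized values of the females were replaced after the first deposit. A difference in level between females and males therefore cannot be told apart from a difference in processing, and female and male levels are not compared here as biology. Genotype was balanced over sex, so each genotype comparison was made within sex and then combined.

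The values lay on regular steps of 0.963 to 1.12 units in females and 0.879 to 1.16 units in males, which corresponds to about 1505981 to 1772888 counts per female and 1243568 to 1518578 counts per male over the panel. All values used for this lay within 0.1 of a step. Whole counts were not recovered from them, because the subtracted background and the floors hide the true zero, so no count test was run. Between replicates, the SD of the log2 difference ranged from 0.191 to 0.462 over pairs, against 0.123 to 0.183 from counting alone. Repeat runs of 1 sample would exceed counting noise too, so the samples were taken as separate mice from their labels alone.

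Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with genotype and sex as additive terms over all 24 mice, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over the 770 genes at a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Because the floors differ, log2 changes of genes near them are not comparable between sexes, and a gene at the floor in the reference or altered group is given as a bound against 20, or against its measured mean where that is higher. The comparisons were GRN KO, TREM2 KO and GRN/TREM2 KO each against WT, GRN/TREM2 KO against GRN KO and against TREM2 KO, and the genotype interaction, which is GRN/TREM2 KO minus GRN KO less TREM2 KO minus WT. Within-sex effects and their difference came from a model with the 8 genotype and sex groups. On simulated data with planted changes of 0.25, 0.5, 1 and 2 (log2) in 50 genes each, the GRN KO test called 70%, 72%, 90% and 100% of them and 1.23% of 570 unchanged genes. The interaction test called 50%, 64%, 86% and 98%, and 0.877% of the unchanged genes. Only 570 of the 770 genes stayed unchanged there, with noise independent between genes, so the adjustment was more lenient than in the data. These shares thus overstate the power of the tests here, most of all for the interaction, where 2 genes passed. A gene that was not called may still have changed.

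Of 19 gene lists fixed before the data were examined, 17 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They covered disease-associated microglia, homeostatic microglia, myeloid cell, complement, lysosome, inflammatory, astrocyte, oligodendrocyte and myelin, neuron and synapse, glutamate, GABA, dopamine and striatal, endothelial and vascular, lipid and cholesterol, oxidative and proteotoxic stress, immediate early and panel housekeeping genes. Lymphocyte genes (3 measured) and choroid plexus and ependymal genes (0 measured) were not tested as lists. On 13 genes the lists overlap, and Gusb stands in the disease-associated microglia, lysosome and housekeeping lists. A second test, chosen after the data were seen, took the mean log2 value of each list per mouse and permuted genotype exactly within sex (400 arrangements, two-sided, smallest p 0.005). It was first run on whole lists, and Grn and Trem2 were left out after their deletion was seen to drive the result, so the values given are without them.

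The genes named were fixed by rule: Grn and Trem2, the 12 largest rises and 12 largest falls among called genes with the same sign in both sexes, up to 4 members per list with the smallest p, and the 5 smallest p where fewer than 5 genes passed. Some genes that the rule selects are not reported here, while counts cover all of them. Genes named in 1 comparison were followed in others, a choice made after their values were seen. Alternatives set beforehand were median, housekeeping and quantile scaling, a pseudocount of 10, a minimum mean of 32, moderation without trend or robust, no sex term, 8 group means, the compared genotypes alone, each sex alone, array weights, an unmoderated test, leaving out each mouse, camera with an estimated correlation, and fry. Added after the data were seen were a common floor of 32, subtraction of the male background with a common floor of 10, and camera without Grn and Trem2. The housekeeping genes served no normalization in the main test. The control probes were used only to describe background and, in the alternative that subtracts the male background, to set its size.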

Results

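Brain RNA of 14-month-old WT, GRN KO, TREM2 KO and GRN/TREM2 KO mice was profiled on 770 panel genes, in 6 mice per genotype with 3 of each sex. Grn encodes progranulin, a secreted and lysosomal protein, and Trem2 encodes a receptor of microglia, the resident macrophages of the brain. The comparisons address what loss of each gene does and whether loss of Trem2 alters the state reached without progranulin. The summed panel signal was 1585509 to 1712167 units in the females and 1334642 to 1462317 units in the males. The mice are separate animals by their labels, so the limma p-values of genes and the exact permutation p-values below measure spread between animals. The camera p-values of lists compare list genes with the other panel genes at a preset correlation, so they do not measure that spread. Of 34 list calls, 2 held with an estimated correlation.

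The deleted genes fitted their labels in all 24 mice. Grn was 1443 ± 8.35 (SD, n = 3) in WT females and 1251 ± 38.3 (SD, n = 3) in WT males. It lay between 1 and 2.57 in females and between 20 and 27.3 in males of the 2 genotypes without Grn, at least 72.1-fold and at least 59-fold lower. Trem2 was 218 ± 93.6 in WT females and 307 ± 34.3 in WT males (SD, n = 3 each), and it lay at the floor in each mouse without Trem2, at least 10.9-fold and at least 15.3-fold lower. In GRN KO, Trem2 itself was 806 ± 192 in females and 596 ± 59.6 in males (SD, n = 3 each). Its difference from WT was 1.93 ± 0.20 (log2, SE) in females, with adjusted p = 1.5e-06, and 0.96 ± 0.20 in males, with adjusted p = 0.0079 (limma within sex). The SE of both sexes rests on a spread pooled over the 8 groups, including those without Trem2, which lay at the floor with almost no spread. It is therefore too small for the females, whose SDs in WT and GRN KO were large, and so is their adjusted p. Over both sexes together the difference was 1.44 ± 0.53 with adjusted p = 0.11, where the spread of this gene also holds the unequal floors of the genotypes that lack it.

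Loss of progranulin raised a set of microglial, complement, lysosomal and astrocyte genes. Cd68, a lysosomal membrane protein of phagocytes, was 3.27-fold higher in GRN KO than in WT (log2 1.71 ± 0.12 SE, adjusted p = 1.1e-09), and the C1q subunits C1qa, C1qb and C1qc, which start the classical complement cascade, were 1.95- to 2.09-fold higher (log2 1.07 ± 0.08 for C1qa and 0.96 ± 0.07 for C1qc, adjusted p = 1.4e-09, 2.7e-11 and 1.6e-09). Gfap, the intermediate filament of reactive astrocytes, was 2.69-fold higher (log2 1.43 ± 0.16, adjusted p = 1.1e-06). For these genes each GRN KO mouse lay above each WT mouse of its sex, a separation that chance gives, counting both directions, to 10% of genes per sex and that the plot of signal per mouse shows for C1qb, Cd68 and Gfap. Of 770 genes, 63 were higher and 7 lower, 70 in all, at an adjusted threshold of 0.05, and each had the same sign in both sexes. Within sex the model called 51 genes in females and 27 in males, 16 of them in both. The unadjusted p was under 0.05 for 147 genes, against 38.5 expected. The split of higher and lower depended on scaling, with 45 higher and 15 lower after median centring, 46 and 13 after housekeeping centring, and 48 and 24 after quantile normalization. The housekeeping mean includes Gusb, which itself rose in GRN KO, and was 0.043 higher there (log2), so this centring builds in part of its own shift.

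**Figure D1:**
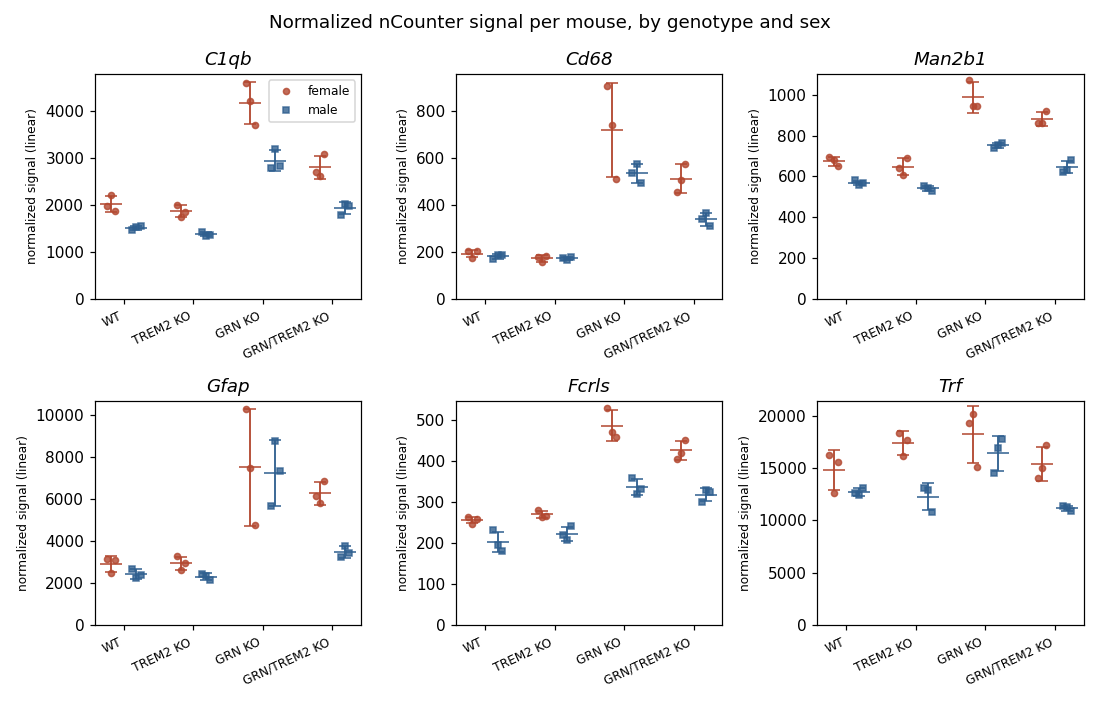
Normalized nCounter signal (linear, vertical axis from 0) of 6 genes in each of the 24 mice, by genotype and sex; points are mice, and bars are the mean ± SD of 3 mice. Cd68 lay between 508 and 906 in GRN KO females and between 455 and 575 in GRN/TREM2 KO females, against 173 to 202 in WT females.

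The disease-associated microglia list, genes known to rise in microglia near pathology, had 7 of 11 measured members higher and none lower. Among them were Cd68, Npc2 and Cybb, while Gusb (lysosomal beta-glucuronidase) rose 1.42-fold and Apoe, a lipid carrier, 1.30-fold. Over the list alone 9 members passed ("adjusted over the list alone"). The list moved up as a set (camera adjusted p = 4.4e-08, and adjusted p = 0.035 with an estimated correlation). In the complement list 6 of 9 members rose, among them C1qb, C3 (2.48-fold), C4a (adjusted p = 0.0028, a probe that near-identical C4b transcripts may also bind) and Clu, and 7 passed adjusted over the list alone. It moved up with adjusted p = 1.3e-09 and adjusted p = 0.035 with an estimated correlation. In the lysosome list 14 of 29 members rose and 1, Grn, fell, with 15 and 1 adjusted over the list alone. Among them Man2b1 (a lysosomal mannosidase) rose 1.39-fold and Npc2 (a cholesterol carrier of the lysosome) 1.48-fold. The list's mean was −0.003 with Grn and 0.266 without it, while its median was 0.108 and the test pointed up (adjusted p = 1.3e-05, and adjusted p = 0.080 with an estimated correlation).

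Of 6 homeostatic microglia genes, which mark resting microglia, Fcrls rose 1.77-fold, while Tmem119 fell by 0.23 (log2, adjusted p = 0.014) and P2ry12 was at −0.13 ± 0.09 (adjusted p = 0.43). That list did not pass as a set against the other panel genes (adjusted p = 0.28), while its mean over mice was 0.18 higher (log2, exact permutation p = 0.005, the smallest possible, adjusted p = 0.014). Its median was 0.026, with 3 of 6 members positive. The permutation sets no list against the rest of the panel, and the housekeeping list reached the same p-values with a mean 0.043 higher. Of 14 myeloid cell genes 6 rose, including Spi1, a myeloid transcription factor, Tlr2 and Hpgds (set adjusted p = 0.0024, and adjusted p = 0.12 with an estimated correlation). Of 9 astrocyte genes Gfap and Aldh1l1 rose (set adjusted p = 0.0048, and adjusted p = 0.25 with an estimated correlation). Of 39 inflammatory genes 6 rose, led by Cxcl16 and Stat3 (set adjusted p = 0.18). Hmox1 and Nfe2l2, of the oxidative stress response, rose 1.63- and 1.33-fold, and their list of 20 did not pass as a set (adjusted p = 0.93). Of 20 oligodendrocyte and myelin genes Bcas1, Trf and Mbp rose (set adjusted p = 0.79). Apoe, Clu and Npc2 made up the 3 of 12 lipid and cholesterol genes that rose (set adjusted p = 0.026, and adjusted p = 0.32 with an estimated correlation). Of 19 endothelial and vascular genes Egfl7 and Nos3 fell and Icam1 rose, with the list down as a set (adjusted p = 0.00065, and adjusted p = 0.32 with an estimated correlation). None of 13 GABA genes passed, although the set pointed down (adjusted p = 0.015, and adjusted p = 0.25 with an estimated correlation). No member passed in the neuron and synapse (46 genes), glutamate (16), dopamine and striatal (11) and immediate early (8) lists, with set adjusted p of 0.28, 0.64, 0.18 and 0.063. The neuron and glutamate lists had means of 0.027 and 0.047 while the test, which is relative to the other panel genes, pointed down. None of the 3 lymphocyte genes passed. Among 12 housekeeping genes Gusb rose and the others did not pass (set adjusted p = 0.79, pointing down with a median of −0.001 and a mean of 0.043).

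Of the rises, 3 called genes had a mean under 32. Mmp12, a macrophage metalloelastase, was at the floor in all WT mice and measured 44.5 ± 19.7 in GRN KO females and 41.3 ± 3.51 in GRN KO males (SD, n = 3 each), at least 2.23-fold and at least 2.06-fold higher. Of the remaining falls, Prkca and Nes were at −0.40 and −0.38 (log2), and these kept their call in 19 and 8 of 24 fits that left out 1 mouse. Mbp kept its call in 11 of 24, and Trf lost its call without WT female replicate 2, GRN KO male replicate 2 or GRN KO male replicate 3. Aldh1l1, Trf and Mbp lost their call after median centring, housekeeping centring and quantile normalization and in females alone, and Clu and Icam1 after quantile normalization.

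Loss of Trem2 alone left the panel close to WT. Of 770 genes only Trem2 passed, and 23 genes had an unadjusted p under 0.05 in limma, against 38.5 expected. The next smallest p belonged to Scamp2, Slc18a2, C1qa and Cers4, at −0.16, −0.85, −0.21 and 0.14 (log2), each with an adjusted p of 1. C1qa differed from WT by −0.21 with a 95% confidence interval of −0.38 to −0.05, and Cd68 by −0.11 with an interval of −0.36 to 0.14. Gfap differed by −0.03, from −0.36 to 0.31, so a change of the size seen in GRN KO lay outside both intervals. The disease-associated microglia list pointed down (camera adjusted p = 0.027) through Trem2, and without Trem2 it had adjusted p = 0.54. Oligodendrocyte and endothelial lists pointed up and down (adjusted p = 0.047 and 0.020), and each had adjusted p = 0.97 with an estimated correlation. The first turned down in males alone and without WT female replicate 2 (adjusted p = 0.85), and the second turned up in females alone.

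Without both genes, part of the progranulin signature was still present. In GRN/TREM2 KO against WT, Cd68 was 2.23-fold higher (log2 1.15 ± 0.12, adjusted p = 8.0e-07), Gfap 1.76-fold (adjusted p = 0.0054) and Fcrls, an Fc receptor-like microglial gene, 1.61-fold (adjusted p = 1.4e-07). C1qb and C1qc were 1.33- and 1.29-fold higher, C1qa was higher by 0.32 ± 0.08 (log2, adjusted p = 0.044), and Man2b1 was 1.22-fold higher. Besides these, C4a and Sgpl1 (sphingosine phosphate lyase) rose. In all, 10 genes were higher, and Grn and Trem2 were the 2 lower. Cd68 was higher by 1.41 ± 0.15 (log2) in females and 0.90 ± 0.15 in males. Gfap was higher by 1.11 ± 0.20 and 0.52 ± 0.20, and the difference between sexes did not pass (adjusted p = 0.80). After median centring 10 genes were higher and 6 lower, 10 and 5 after housekeeping centring, and 12 and 5 after quantile normalization. Sgpl1 kept its call in 15, and C1qa and C4a in 8, of 24 fits that left out 1 mouse, and Csf1r, the receptor for a microglial growth factor, was at −0.17 ± 0.05 (adjusted p = 0.10). Lists of complement (4 of 9 rose, adjusted p = 1.5e-05), lysosome (3 of 29 rose, adjusted p = 1.5e-05) and disease-associated microglia genes (1 of 11 rose and Trem2 fell, adjusted p = 0.015) pointed up, and the oligodendrocyte list pointed down (adjusted p = 0.0016, no member passing, and up in females alone). With an estimated correlation these had adjusted p = 0.20, 0.19, 0.61 and 0.61. The means of the lysosome and disease-associated microglia lists were −0.123 and −0.238 through the deleted genes, against 0.144 and 0.265 without them. Over mice, the complement list was 0.23 higher and the lysosome list 0.14 higher without the deleted genes (log2, exact permutation p = 0.005, the smallest possible, adjusted p = 0.043).

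**Figure D2:**
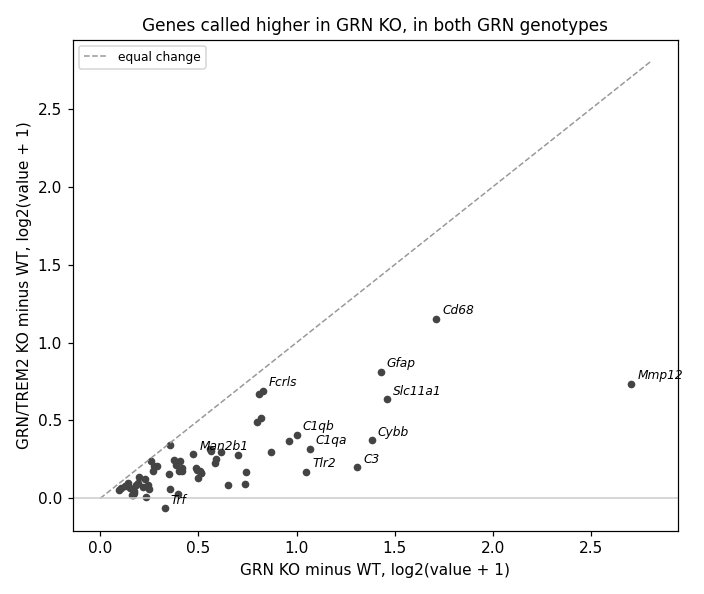
Difference of GRN/TREM2 KO from WT (vertical axis) against that of GRN KO from WT (horizontal axis), on the log2(value + 1) scale, for the 63 genes called higher in GRN KO; each point is a gene, and the dashed line marks equal change. All 63 points lie below the line, and 62 lie above 0. The genes were chosen on the same GRN KO and WT mice, which by itself favours points below the line and above 0.

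When GRN/TREM2 KO was set against GRN KO directly, 16 genes were lower and none higher. Apart from Trem2 they included C1qa, lower by −0.75 ± 0.08 (log2, adjusted p = 1.2e-06), C1qb by −0.59 ± 0.06 (adjusted p = 3.0e-07) and C1qc by −0.59 ± 0.07 (adjusted p = 1.1e-05). Gusb fell by 0.34 and Cd68 by 0.56 (adjusted p = 0.017), and Hmox1, Cxcl16, Tlr2, Mmp12, Man2b1, Stat3, Gfap and Gtf2a1 were lower too, the last named after its value was seen. Gfap differed by −0.19 ± 0.20 in females and −1.04 ± 0.20 in males, where the difference between sexes had adjusted p = 0.45, and its call was kept in 5 of 24 fits that left out 1 mouse. Stat3 kept its call in 8 and Tlr2 in 12 of these fits, while Cd68, Hmox1 and Trf lost theirs only without GRN/TREM2 KO male replicate 3. Trf, transferrin of oligodendrocytes, was lower by −0.39 ± 0.09 (adjusted p = 0.018). Fcrls was at −0.14 ± 0.06 (95% confidence interval −0.27 to −0.01, adjusted p = 0.30). The model called 7 genes in females and 28 in males, 4 of them in both. The count was 52 without GRN KO female replicate 3, 10 without GRN KO female replicate 1 and 6 without GRN/TREM2 KO male replicate 3. After quantile normalization 6 genes were higher and 14 lower, and Trf and Tlr2 lost their call. Man2b1, Mmp12, Tlr2, Stat3 and Gfap lost theirs after median centring, and Stat3 and Gfap after housekeeping centring.

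Fixed lists fell in the same comparison. Complement genes (3 of 9 fell, 6 adjusted over the list alone, adjusted p = 3.5e-08), disease-associated microglia genes (3 of 11 with Trem2, 8 adjusted over the list alone, adjusted p = 5.4e-07, and adjusted p = 0.00021 without Trem2), myeloid cell genes (1 of 14, adjusted p = 0.0039), oligodendrocyte genes (1 of 20, adjusted p = 0.0032) and lysosome genes (4 of 29, adjusted p = 0.012) pointed down, and endothelial genes up with no member passing (adjusted p = 0.0054). With an estimated correlation these had adjusted p = 0.061, 0.061, 0.17, 0.47, 0.47 and 0.47. Over mice, the complement, disease-associated microglia and lysosome lists were lower by −0.53, −0.40 and −0.12 without the deleted genes (log2, each exact permutation p = 0.005, the smallest possible, adjusted p = 0.028). The oligodendrocyte list differed by −0.05 in females and −0.33 in males, with an exact permutation p of 0.07 over mice.

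**Figure D3:**
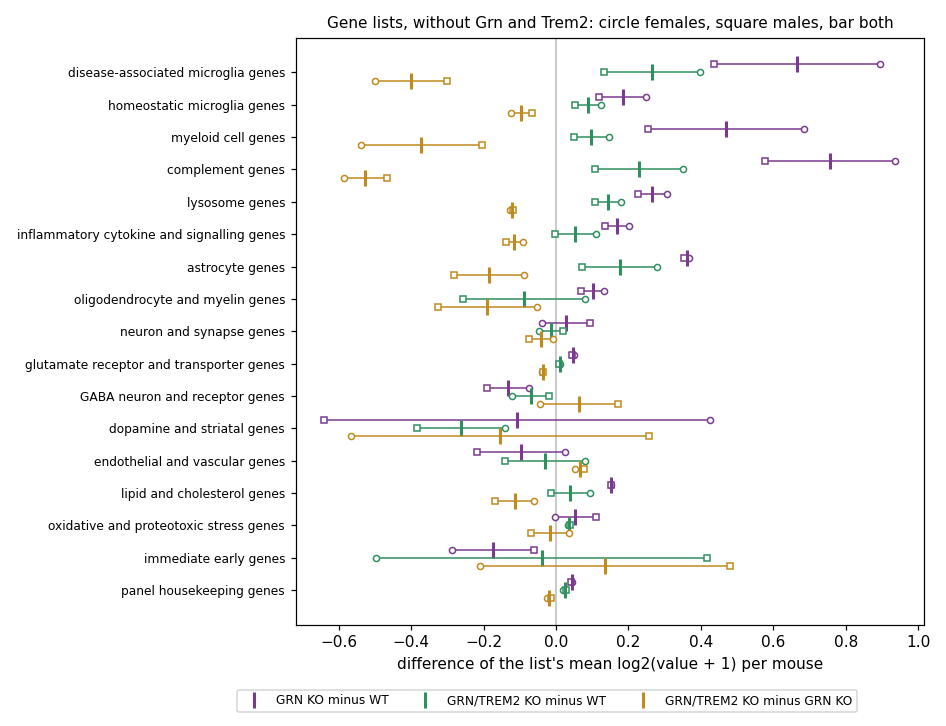
Difference of each list's mean log2(value + 1) per mouse (horizontal axis), without Grn and Trem2, for GRN KO minus WT, GRN/TREM2 KO minus WT and GRN/TREM2 KO minus GRN KO; circles are females, squares are males and upright bars the mean of both. The complement list lay at 0.76, 0.23 and −0.53 in these comparisons.

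Loss of Grn on the Trem2-deficient background, GRN/TREM2 KO against TREM2 KO, raised 14 genes and lowered Grn. Cd68 was 2.40-fold higher (log2 1.26 ± 0.12, adjusted p = 3.2e-07), Gfap 1.79-fold (adjusted p = 0.0024) and Hpgds, a prostaglandin D synthase, 1.45-fold. Fcrls was higher by 0.58 ± 0.06 (log2, adjusted p = 1.3e-06), C1qb, C1qa and C1qc by 0.53 each, and Man2b1 1.28-fold. C4a, Sgpl1, Scamp2, Bax and Gnai3 rose as well, the last named after its value was seen. Cd68 was higher by 1.56 ± 0.15 (log2) in females and 0.97 ± 0.15 in males. After quantile normalization 10 genes were higher and 5 lower, and C4a, Bax and Scamp2 kept their call in 11, 15 and 22 of 24 fits that left out 1 mouse. These 3 lost it after housekeeping centring and after quantile normalization. Complement (4 of 9 rose, adjusted p = 0.00016), disease-associated microglia (1 of 11, adjusted p = 0.00013) and lysosome genes (3 of 29, adjusted p = 0.00091) pointed up and oligodendrocyte genes down (adjusted p = 3.2e-05, no member passing). With an estimated correlation these had adjusted p = 0.27, 0.27, 0.27 and 0.60. The lysosome mean was −0.126 with Grn and 0.139 without it.

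The genotype interaction asks whether loss of Trem2 had another effect without progranulin than with it. C1qb and C1qa passed, at −0.47 ± 0.08 (adjusted p = 0.0062) and −0.53 ± 0.11 (adjusted p = 0.038). They were lower by more on the GRN KO than on the WT background, by −0.46 and −0.47 in females and males for C1qb and by −0.51 and −0.56 for C1qa. C1qc, Trf and Gusb had the next smallest p, at −0.43, −0.48 and −0.37, with adjusted p = 0.11, 0.17 and 0.17. The unadjusted p was under 0.05 for 87 genes, against 38.5 expected. Neither C1qb nor C1qa passed with females alone or males alone. C1qa kept its call in 6 of 24 fits that left out 1 mouse, and after quantile normalization 1 gene was higher and 4 lower. The complement list pointed down (2 of 9 fell, adjusted p = 2.5e-06), as did disease-associated microglia, lysosome, myeloid, oligodendrocyte, astrocyte and homeostatic microglia genes, while endothelial and immediate early genes pointed up. With an estimated correlation the adjusted p was 0.24 for complement and 0.35 for each of the other lists.

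Over the 63 genes called higher in GRN KO, the median difference from WT was 0.42 (log2) in GRN KO, 0.18 in GRN/TREM2 KO and −0.007 in TREM2 KO. The median difference of GRN/TREM2 KO from GRN KO was −0.24, and all 63 genes were lower. Because the choice of genes used the same GRN KO and WT mice, it biases the differences from both. Genes were therefore also chosen in one sex and measured in the other. Of 59 genes chosen in females at an unadjusted p under 0.01, 56 were lower in GRN/TREM2 KO than GRN KO males, with a median of −0.23. Of 60 chosen in males, 46 were lower in females, with a median of −0.06. In the measuring sex, the median difference of GRN KO from WT was 0.322 for the first set and 0.143 for the second. Against WT, 39 of the 59 and 41 of the 60 were higher in GRN/TREM2 KO of the other sex, with medians of 0.089 and 0.055. The log2 change from WT in GRN/TREM2 KO, as a percentage of the log2 change in GRN KO, differed between genes. It was 83.5% for Fcrls, 83.4% for C4a, 67.5% for Cd68, 40.9% for C1qb, 29.7% for C1qa and 15.2% for C3, with a median of 42.9% and no test between genes. This is a ratio of log2 changes rather than of signal, and the choice of genes on the same mice biases it too. These genes were picked after their values were seen.

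Sexes were compared only in the size of the genotype effect, since their levels carry different processing. A sex difference passed for Grn, Mmp12 and Slc11a1 in GRN KO against WT, for Trem2 in TREM2 KO, for Grn and Trem2 in GRN/TREM2 KO against WT, for Trem2 against GRN KO and for Grn against TREM2 KO. Each of these genes lay at or near the floor in at least 1 group, where the floors of the sexes differ. For the interaction no sex difference passed in limma, and 48 genes had an unadjusted p under 0.05.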

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

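Of the tests in this part, the subtraction of the male background with a common floor, the common floor of 32, the makeup of the splits, and the checks of Grn scale and of Mmp12 and Slc11a1 were chosen after the results were seen.

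Sex differences in the genotype effect (female minus male, log2) passed the test of the difference itself for 4 genes. For Grn they were −3.29 in GRN KO against WT, −3.71 in GRN/TREM2 KO against WT and −3.72 in GRN/TREM2 KO against TREM2 KO. For Trem2 they were −2.80 in TREM2 KO against WT, −2.80 in GRN/TREM2 KO against WT and −3.77 in GRN/TREM2 KO against GRN KO. Mmp12 differed by 3.40 ± 0.57 and Slc11a1 by 2.16 ± 0.43 in GRN KO against WT.

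Unequal floors, near 1 in females and 20 in males, are a candidate explanation. With the male background subtracted and both sexes raised to 10, 1 gene, Grn, kept a called difference, at −0.24 ± 0.04 in GRN/TREM2 KO against TREM2 KO (adjusted p = 0.038), and with both sexes raised to 32 Grn kept it in 3 comparisons, so floors alone are not its whole cause. At the floor of 32 the Grn difference was −0.207 in both comparisons of mice without Grn against WT, where all mice without Grn lay at the floor. It thus mirrors the WT level of the sexes, which differed by 0.207 ± 0.026 against 0.211 ± 0.006 for housekeeping genes. That leaves −0.005 ± 0.022, so an unequal scale may account for the difference against WT. The difference against TREM2 KO was not set against the level of the TREM2 KO mice. Mmp12 went to 1.01 ± 0.28 (adjusted p = 0.15) and Slc11a1 to 1.30 ± 0.28 (adjusted p = 0.051), since the low female values were raised to 10. With both sexes raised to 32 they went to 0.11 ± 0.21 (adjusted p = 0.914) and 0.125 ± 0.116 (adjusted p = 0.76), where most values of both genes lie at that floor, so floors and a sex effect cannot be told apart for these 2 genes near the floor. A biological sex difference stays open and untested.

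The numbers of sex differences called were 3, 1, 2, 1 and 1 in the 5 pairwise comparisons, in the order GRN KO, TREM2 KO and GRN/TREM2 KO against WT, then GRN/TREM2 KO against GRN KO and TREM2 KO. Of 100 splits of the mice within sex, 12, 7, 7, 15 and 10 called as many, with highest other counts of 62, 1, 13, 39 and 9. Of the other splits among these, 11 of 11, 5 of 6, 5 of 6, 13 of 14 and 7 of 9 exchanged unequal numbers of females and males, which turns the genotype effect itself into a sex difference. The split calling 62 genes kept genotype in the males and exchanged 2 of 3 females of each genotype. These splits therefore do not settle whether chance gave the counts.

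Mice far from the others of their genotype, by the gap to the nearest mouse over the range of 6 after removal of the sex effect, occurred in 13 of 156 groups tested, where 7.8 are expected by chance. WT female replicate 2 was lowest in Bcas1 (0.871), Mbp (0.711) and Trf (0.786), which are all oligodendrocyte genes. GRN/TREM2 KO female replicate 3 was highest in C1qa (0.659) and C1qc (0.688). GRN KO male replicate 3 was highest in Aldh1l1 (0.812), and GRN KO female replicate 1 was highest in Man2b1 (0.776). In TREM2 KO, female replicate 2 was lowest in C1qc (0.76), female replicate 1 was lowest in Cxcl16 (0.651) and highest in Icam1 (0.766), and male replicate 3 was highest in Osmr (0.63). GRN/TREM2 KO male replicate 1 was lowest in Osmr (0.642). Without WT female replicate 2, Trf and Mbp lost their call in GRN KO against WT and Bcas1 kept its call.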

How the results depend on the processing

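The common floor of 32, the subtracted male background with a floor of 10, camera without Grn and Trem2 and the list mean per mouse were added after the data were seen; the cause of the shifts below was not tested beyond the smaller number of mice in fits of 1 sex or 2 genotypes. The alternatives were run for the called genes under the naming rule and the smallest p where fewer than 5 passed, and none of these turned its direction. Of the calls, 30 of 37 in GRN KO against WT, 8 of 12 in GRN/TREM2 KO against WT, 6 of 15 against GRN KO, 11 of 14 against TREM2 KO and 1 of 2 in the interaction were kept whichever mouse was left out, and Trem2 was kept in TREM2 KO. The median of GRN/TREM2 KO minus GRN KO over the genes called in GRN KO stayed below 0 in all settings, between −0.37 and −0.06. In this paragraph and the next, called genes are listed as GRN KO, GRN/TREM2 KO against WT, against GRN KO and against TREM2 KO, and the interaction, with 70, 12, 16, 15 and 2 as reported.

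Without a sex term the counts were 29, 5, 2, 5 and 0. Females alone gave 37, 5, 2, 7 and 1, and males alone 31, 6, 29, 6 and 3, with none of the interaction genes of either sex among the 2 reported. With array weights GRN/TREM2 KO gave 23, 53 and 24 and the interaction 7. Against GRN KO, median centring gave 10 and the compared genotypes alone 5. The interaction count was 5 after quantile normalization, 4 with 8 group means, 4 with the male background subtracted, 1 without a trend and 1 unmoderated. Leaving out 1 mouse moved the count against GRN KO between 6 and 52 and the interaction between 1 and 9, with 9 without GRN KO female replicate 3 and 6 without GRN/TREM2 KO female replicate 3. TREM2 KO gave 1 gene in every setting run.

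Sex differences called (3, 1, 2, 1 and 1 as reported) were 0 in all 5 comparisons after quantile normalization. They were 1, 0, 1 and 0 in the first 4 at the common floor of 32, and 0, 0, 0 and 0 with the male background subtracted. A pseudocount of 10 gave 0 for TREM2 KO and 1 for GRN/TREM2 KO against WT, the minimum mean of 32 gave 1 for GRN KO, and array weights gave 5 for GRN KO and 2 for GRN/TREM2 KO against GRN KO. Leaving out 1 mouse gave 2 to 7 for GRN KO, 1 to 2 for GRN/TREM2 KO against GRN KO (2 without GRN KO female replicate 2) and 1 to 2 against TREM2 KO (2 without GRN/TREM2 KO female replicate 1). The 7 came without WT female replicate 2, and 5 without GRN KO female replicates 1 or 3 or GRN KO male replicate 3.

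Of 34 list calls, 2 held with an estimated correlation, 16 with fry and 32 without Grn and Trem2, and 15 of the 25 pairwise ones held for the list mean per mouse. The oligodendrocyte list turned down in TREM2 KO in males alone (adjusted p = 0.000142) and without WT female replicate 2 (adjusted p = 0.85, with 0.000619 to 0.851 over fits that left out 1 mouse), and up in GRN/TREM2 KO against WT in females alone (adjusted p = 0.49). The endothelial list turned up in TREM2 KO in females alone (adjusted p = 0.94). Signal limits the genes near the floors: 12 genes lay at the floor in all females and 17 in all males. No paired analysis was possible because the labels give no numbers shared between groups.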

Other observations

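The comparison of C1q genes with homeostatic markers and the permutation of list means per mouse (complement and oligodendrocyte lists) and the makeup of the splits were chosen after the results were seen, and the other tests in this part were fixed before them.

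Markers of resting microglia did not follow the C1q genes. The mean of P2ry12, Tmem119, Cx3cr1 and Csf1r was at −0.08 ± 0.05 (log2, SE) in GRN KO against WT, with exact permutation p = 0.16, and at −0.10 ± 0.04 in GRN/TREM2 KO, with exact permutation p = 0.02. The mean of C1qa, C1qb and C1qc was 1.01 ± 0.08 higher in GRN KO (exact permutation p = 0.005, the smallest possible). In TREM2 KO the same mean was −0.17 ± 0.05 against WT, with exact permutation p = 0.01, at −0.16 in females and −0.17 in males, although none of these 3 genes passed over the panel. These p-values are two-sided. Adjusted over the 15 values of this kind they were 0.185, 0.0273, 0.00833 and 0.015 in the order given.

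The rise of complement, lysosome and microglia genes in GRN KO could come from more microglia in the tissue. That would raise resting markers by about as much as C1q. The C1q mean rose by 1.087 ± 0.108 more than the mean of the 4 markers, at 1.07 in females and 1.10 in males, which argues against a larger number of otherwise unaltered microglia as the whole cause. A change in the state of the microglia, with lower expression of such markers per cell and more cells, stays open, since whole-brain RNA cannot separate number from state.

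Lower levels of the GRN KO genes in GRN/TREM2 KO could come from choosing the genes on the same GRN KO mice. The cross-sex medians were −0.226 and −0.06, and the second lay between the bounds set for either outcome, so for the chosen genes the 2 readings cannot be told apart. The bounds took no account of the rise to be lost. In the measuring sex the median difference of GRN KO from WT was 0.322 for the first set and only 0.143 for the second. The complement list, with members fixed without these data, was lower by −0.527 over mice (exact permutation p = 0.005, adjusted over the lists p = 0.028). That argues against the choice of single genes as the cause for that list. The list itself was picked after the results were seen, and it had the smallest camera p of the lists in GRN KO against WT. The genotype interaction, which tests an effect of Trem2 loss that depends on Grn, passed for C1qb (adjusted p = 0.0062) and C1qa (adjusted p = 0.038), and for the other chosen genes such an effect stays open.

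Chance was tested by splitting the mice of the compared genotypes otherwise within sex, over 100 splits with the real one. The real split alone reached 70 genes in GRN KO against WT (1 of 100, highest other 34), 1 in TREM2 KO (1 of 100, highest other 0), 12 in GRN/TREM2 KO against WT (1 of 100, highest other 6) and 15 against TREM2 KO (1 of 100, highest other 4). For GRN/TREM2 KO against GRN KO 2 splits reached 16 genes. The other called 48 and differed from the real split only by exchanging GRN KO female replicate 3 with GRN/TREM2 KO female replicate 3, and leaving out the first of these mice gave 52. For the interaction, genotype was shuffled over all mice within sex. Of 100 arrangements with the real one, 2 reached 2 genes, and the highest other called 3. These shuffles also break up the effect of Grn loss and add it to the spread, so they cannot decide on chance for the interaction. In the pairwise comparisons other than TREM2 KO against WT, the share of splits that reached the real count was under 0.05. That argues against chance as the source of these counts, least firmly against GRN KO, where another split called 48. The counts include deleted genes, whose change the genotype fixes. Without these they were 69 and 10 for GRN KO and GRN/TREM2 KO against WT, 15 against GRN KO and 14 against TREM2 KO. In TREM2 KO against WT the gene was the deleted Trem2 itself, and the split shows nothing further.

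Across 768 genes, without the deleted ones, the differences of GRN KO and GRN/TREM2 KO from WT correlated with r = 0.606 and a covariance of 0.0267. Unchanged groups sharing the WT mice gave a mean r of 0.479, with 95% of 100 draws between 0.187 and 0.741, and a covariance of 0.0135. With GRN KO from one sex and GRN/TREM2 KO from the other, which share no mice, r was 0.045 and 0.324 and the covariance 0.00286 and 0.0230. All 10 genes called higher in GRN/TREM2 KO were among the 63 of GRN KO, where independent lists would share 0.82, although both comparisons use the same WT mice. Genes are not independent replicates.

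The oligodendrocyte list was to be set against the share of white matter by a test written before its result was seen, and after the result it was not weighed further, so its values stand here alone. It differed by −0.19 between GRN/TREM2 KO and GRN KO over mice (log2, exact permutation p = 0.07, adjusted p = 0.18), at −0.05 in females and −0.33 in males.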
